A study of Mus musculus with 10 samples.

How the data were processed

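Total RNA from whole hearts of 10 mice with floxed Tsg101 alleles was measured by RNA sequencing. Per the labels, RNA was extracted with the RNeasy Mini Kit, and libraries were made from 1 microgram of RNA with the VAHTS Universal V10 RNA-seq kit. Vectors were given on postnatal day 0 and hearts taken on postnatal day 10, with 5 animals per group. Groups and replicate numbers came from the sample titles (Cre group 1, 3, 4, 5 and 6, control group 10, 11, 12, 13 and 16). The labels give no sex, litter or batch.

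The authors deposited 1 table of TPM (read counts divided by gene length and scaled to the same total in every library) for 55858 genes, 1 column per library. The submitters' processing notes name bcl2fastq, Trimmomatic 0.32, FastQC 0.11.7, STAR 2.7.1, Picard 1.96, HTSeq 0.11.2 and DESeq2 1.22.2 and the mouse build mm10, with no role or order. The annotation release, the strand setting, the gene lengths and any filter are not given in the sources used here. Genes that overlap, antisense partners and near-identical copies could therefore share or split reads in ways that cannot be checked. Of the 55858 identifiers, 51460 matched the GENCODE M21 annotation without their version number and 35 with it, so the release differs and no coordinates are printed. Symbols came from the table, and 143 of them stand on more than 1 row.

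TPM keeps no total count, so depth per library is unknown, and no counting intervals are given. Relative depth was estimated from values under 0.1 TPM, as the TPM worth of 1 read relative to control 10. A TPM value is a share, so a change in abundant transcripts moves all other values. Mitochondrially encoded genes held 40.9 to 51.6% of TPM and the 20 most abundant genes 49.5 to 61.1%. Low values rest on few reads, and 26751 genes had no value above 0.

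From the TPM values, log2(TPM + 1) was computed and tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no covariate) over the 13054 genes with a mean TPM of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes are from this test, and log2 differences are Cre minus control on the log2(TPM + 1) scale. Library measures, 12 in all, were compared by exact two-sided permutation over the 252 labelings of the 10 libraries, whose smallest p is 0.00794. After Benjamini-Hochberg adjustment over the 12, the sarcomere share had an adjusted p of 0.0317, the share of the 20 most abundant genes and the number of genes at 1 TPM or more 0.0381, Tsg101 in TPM 0.0952, the mitochondrial share 0.107 and relative depth 0.429.

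Lists of genes for cardiac programs, library quality and cell types were fixed before the data were examined. They hold 856 genes, 1 of which was not found. The 36 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and beside it with an estimated correlation, with fry and with ranks. Named genes were also chosen by a rule set then. The rule takes Tsg101, the 10 largest increases and 10 largest decreases among called genes with a mean TPM of at least 5 and no overlap between groups (leaving out gene models without an ordinary symbol), and up to 3 members of each list with the smallest adjusted p, or the most abundant member of a list with none. It adds Bin1, Jph2, Cav3, Ryr2, Cacna1c, Atp2a2, Nppa, Nppb, Myh6 and Myh7 whatever their test. Other list members that are named (such as Casq2, Tcap, Tnni3, Acta1, Hmox1, Map1lc3a, Ctsf, Chmp4c, Vps28, Ldhb, Slc2a4, Eln, Nr4a1, Lyve1, Mertk, Ddit3, Atf3, S100a1 and Sri), and Gm3776, were chosen after their values were seen.

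The gene and list tests were tested on simulated data with the real means and spread. Of 100 genes changed by 0.5 log2 units, 63% were recovered, and of 100 changed by 1 log2 unit, 96%. Of 169 calls 10 were false, and data with no change gave 0 calls. A shift of 0.4 log2 units given to the sarcomere list was estimated at 0.382, and no other list was called. The simulated genes varied independently of one another, so this does not test the list calls where genes are correlated. In the gene simulation as many genes were raised as lowered, so it does not test calls under a shift of most genes to one side.

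Alternatives planned before the data were examined were pseudocounts of 0.1 and 5 TPM, no filter on low values, a mean TPM of at least 5, median-of-ratios scaling over genes with a mean TPM of at least 10, quantile normalization, rescaling without mitochondrially encoded genes, robust eBayes, array weights, the level of Y-linked genes or the first residual component as a covariate, each library left out in turn, and the other list tests. Alternatives chosen after seeing the data were protein-coding genes only, and median-of-ratios scaling or rescaling without mitochondrially encoded genes with the library labelled Cre 4 left out too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The values of 2 genes are not reported here.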

Results

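Total RNA from the hearts of 10 mice was sequenced, with 5 animals per group. All animals carried floxed alleles of Tsg101, which encodes a subunit of ESCRT-I, part of the endosomal sorting machinery that buds and cuts membranes away from the cytosol. On postnatal day 0 they received an adeno-associated virus of serotype 9 (AAV9) with the cardiac troponin T promoter, which is active in cardiomyocytes. In the Cre group the vector carried Cre recombinase and EGFP (libraries Cre 1, 3, 4, 5 and 6). In the control group it carried EGFP without Cre (libraries control 10, 11, 12, 13 and 16). Hearts were taken on postnatal day 10. The series concerns the ESCRT machinery in the formation of T-tubules, the membrane invaginations of cardiomyocytes, so the comparison asks how deletion of Tsg101 changed the cardiac transcriptome. Cre is present in only one of the groups, so effects of Cre and of the loss of Tsg101 vary together here. The values are TPM, read counts divided by gene length and scaled to the same total in every library, which keep no total read count, so absolute depth is unknown. From the steps between low values, 1 read was worth between 1.00 and 1.59 times its TPM in control 10, and the groups overlapped in this measure (exact permutation test, two-sided, p = 0.333).

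Tsg101 (ENSMUSG00000014402.16) was lower in the Cre group, at 31.1 ± 6.30 TPM (SD, n = 5) against 38.7 ± 1.5 TPM (SD, n = 5) in controls, or 80.3% of the control mean. The log2 difference was -0.33 ± 0.11 (SE), with a limma adjusted p = 0.0285 and an exact permutation p = 0.0476. The library labelled Cre 4 went against its label. It held 42.0 TPM, above the highest control (40.0 TPM), whereas Cre 1, 3, 5 and 6 lay between 26.8 and 31.0 TPM. Without the library labelled Cre 4 the Cre mean was 73.3% of the control mean (log2 difference -0.44, limma adjusted p = 0.000171). After median-of-ratios scaling of all 10 libraries the Cre mean was 69.0% of the control mean (log2 difference -0.53, limma adjusted p = 0.000727). The call at the deposited scale was lost when Cre 1, 5 or 6 or control 10, 12 or 13 was left out (adjusted p from 0.0539 to 0.0698) and without the filter on low values (adjusted p = 0.0668). A value per gene in whole heart also counts transcripts of cells other than cardiomyocytes and of exons that Cre leaves in place, so it gives no deletion efficiency.

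The groups differed across much of the transcriptome. Of 13054 genes tested, 5889 passed an adjusted p of 0.05, 4593 of them higher and 1296 lower in the Cre group, so 78.0% of calls were higher. A difference of at least 1 log2 unit was reached by 453 of the higher and 147 of the lower genes. This split depends on scaling, because TPM is a share of a fixed total and the median tested gene stood 0.16 log2 units higher in the Cre group. The 20 most abundant genes of each library held 55.7 ± 3.69% of TPM in the Cre group and 60.1 ± 0.928% in controls, and 13160 ± 172 against 12840 ± 89.8 genes reached 1 TPM (SD, n = 5 each; exact permutation p = 0.0159 for both). Median-of-ratios scaling moved that median by -0.18, to -0.02, and gave 5017 calls, 2445 higher and 2572 lower (48.7% higher). All 1296 genes lower at the deposited scale and 2445 of the genes higher there were called in the same direction under both, and none in opposite directions. This overlap follows from the scaling and is no separate support. It divides the Cre libraries by 1.01 to 1.16 and the controls by 0.910 to 0.950, which moves nearly all genes down alike. A gene at +0.16 at the deposited scale is therefore at the middle of the tested genes. Without the library labelled Cre 4, 5652 genes passed, 4303 higher and 1349 lower. The first principal component held 47.9% of the variance and separated the groups. The library labelled Cre 4 was at -35.0, next to the other Cre libraries at -34.0 to -20.4 and opposite controls at 25.4 to 30.3. On the second component (9.76%) that library stood apart at -26.5, with other Cre libraries at -5.94 to 17.8 and controls at -11.2 to 16.3.

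**Figure D1:**
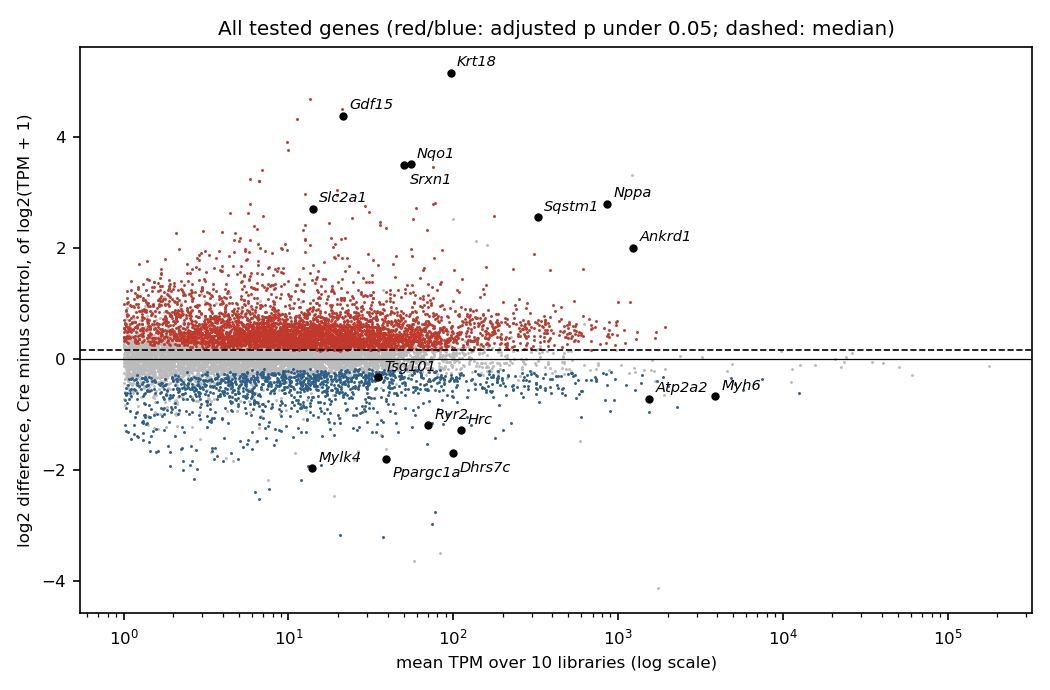
Log2 difference of log2(TPM + 1), Cre minus control, of the 13054 tested genes against mean TPM over 10 libraries on a log axis, with genes past an adjusted p of 0.05 in red (higher) or blue (lower). The dashed line marks the median of 0.16, and most called genes (4593 of 5889) lie above 0 at this scale.

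The largest increase in log2(TPM + 1) among tested genes was in Krt18 (ENSMUSG00000023043.8), an intermediate filament keratin of simple epithelia, at 188 ± 32.4 TPM in the Cre group and 4.23 ± 0.526 TPM in controls (SD, n = 5 each), a log2 difference of 5.16 ± 0.12 (SE; limma adjusted p = 2.59e-10). Its partner keratin Krt8 rose by 4.51 on the same log2(TPM + 1) scale, which understates the change of low genes and is used for all rises and falls given here. Gdf15, a secreted stress-induced cytokine, was 41.8 ± 6.96 TPM against 1.05 ± 0.432 TPM, a log2 difference of 4.39 (limma adjusted p = 3.43e-09). Tubb3, a beta tubulin typical of neurons, rose by 3.77, and Sprr1a, a small proline-rich protein, by 3.41. The redox enzymes Nqo1 and Srxn1 rose by 3.51 and 3.50, and the metal-binding metallothionein Mt2 by 3.47. Of the glutathione S-transferases, Gsta1 rose by 3.92, and Gsta2 was listed at 0 in 4 control libraries and at 0.202 TPM in control 11, against 14.5 to 36.2 TPM in the Cre group. Gsta1 and Gsta2 are near-identical paralogs, and a further copy in the table, Gm3776, also rose by 4.33, so their separate values are uncertain.

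The largest decreases included Mylk4, of the myosin light chain kinase family, which was 5.17 ± 1.35 TPM in the Cre group and 22.6 ± 3.64 TPM in controls (SD, n = 5 each; log2 difference -1.96, limma adjusted p = 3.37e-06). Ppargc1a, the coactivator that drives mitochondrial biogenesis, was 16.5 ± 2.36 TPM against 62.2 ± 21.8 TPM (log2 difference -1.79, limma adjusted p = 6.37e-05). Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, was 47.1 ± 8.55 TPM against 153 ± 13.2 TPM (log2 difference -1.69, limma adjusted p = 9.36e-07). Clec3b fell by 1.92, Spata6l by 1.61, Krt222 by 1.58, the retinoid receptor Rxrg by 1.54, the carbonic anhydrase Car14 by 1.52 and the phospholipase Pla2g5 by 1.47. Rmrp (ENSMUSG00000115420.2), the RNA of a small ribonucleoprotein, fell by 2.96 (limma adjusted p = 0.0257; log2 difference -3.554 to -1.988 with 1 library left out). It is uncertain, since its symbol is on more than 1 row, Cre 6 is listed at 0, and its call was lost without Cre 1 (adjusted p = 0.0580) or control 11 (adjusted p = 0.0518), with a pseudocount of 0.1 TPM (0.0576), with robust eBayes (0.0649) and without the filter (0.0797). Its Cre values reached 76.0 TPM, below the lowest control at 85.5 TPM.

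**Figure D2:**
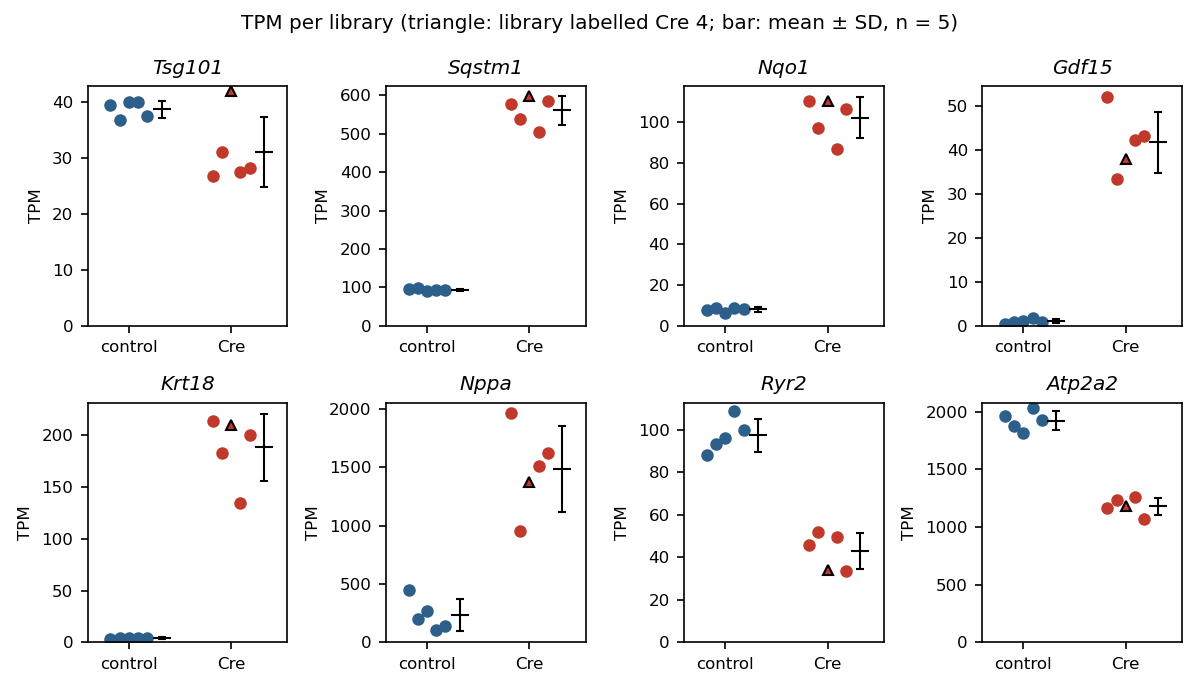
TPM per library of 8 genes in control (blue) and Cre (red) hearts, with the group mean and SD (n = 5 each) as black bars and the library labelled Cre 4 as a triangle. For Tsg101 the triangle lies at 42.0 TPM, above the controls, while for the other 7 genes it lies with the Cre group.

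Among genes of the T-tubule and of the calcium release machinery it faces, more fell than rose in the Cre group. Of the 20 tested genes of the T-tubule and dyad list, 9 fell, 2 rose and 9 did not pass. Sarcomere genes were lower in the same libraries too, with a list median of -0.43 against -0.14 for the T-tubule and dyad list. The ryanodine receptor Ryr2, the calcium release channel of the sarcoplasmic reticulum, was 43.0 ± 8.53 TPM against 97.3 ± 7.76 TPM (SD, n = 5 each; log2 difference -1.18 ± 0.12 SE, limma adjusted p = 1.92e-05). The L-type channel subunits Cacnb2 and Cacna2d1 fell by 1.13 and 0.75, and Tcap, a Z-disc cap of titin, by 1.41. Jph2, the junctophilin that ties T-tubule to sarcoplasmic reticulum, fell by 0.31 (74.3 ± 5.67 against 92.5 ± 3.37 TPM, limma adjusted p = 0.00175). Bin1, which bends T-tubule membrane, was 10.1 ± 1.58 TPM against 7.73 ± 1.02 TPM (log2 difference 0.34, limma adjusted p = 0.0302). That call was lost under median-of-ratios scaling (log2 difference 0.15, adjusted p = 0.284) and without Cre 1, 4 or 5 or control 11 or 12 (adjusted p from 0.0569 to 0.0727). Cav3, a muscle caveolin, was 64.9 ± 11.5 TPM against 61.7 ± 3.38 TPM (adjusted p = 0.687), and Cacna1c, the pore of the L-type channel, was 27.3 ± 2.18 TPM against 26.9 ± 2.56 TPM (adjusted p = 0.874). Neither differed by more than the replicate spread, and both had a negative difference under median-of-ratios scaling (-0.15 and -0.19). As a set the list was lower than other genes (camera adjusted p = 3.35e-05; adjusted p = 0.183 with an estimated correlation). Adjusted over the list alone, the counts of this and the other lists are the same unless another count is given.

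In the sarcoplasmic reticulum calcium handling list, 10 of 16 genes fell and 2 rose (11 fell and 2 rose adjusted over the list alone). The calcium pump Atp2a2 was 1178 ± 74.0 TPM against 1922 ± 81.6 TPM (SD, n = 5 each; log2 difference -0.71, limma adjusted p = 3.99e-06). The calcium-binding Hrc fell by 1.27, the pump inhibitor Pln by 0.95 and the calcium store protein Casq2 by 0.62, while the risen genes were S100a1 and Sri. The camera test gave an adjusted p = 2.5e-08 (adjusted p = 0.134 with an estimated correlation). In the sarcomere list, 14 of 20 genes fell and none rose (15 fell adjusted over the list alone; camera adjusted p = 3.55e-12, adjusted p = 0.134 with an estimated correlation). Actn2 fell by 0.63, Ldb3 by 0.55 and Tnni3 by 0.86. Myh6, the adult myosin heavy chain, was 3035 ± 496 TPM against 4767 ± 72.7 TPM (log2 difference -0.67, limma adjusted p = 0.000262). These sarcomere genes together held 4.16 ± 0.527% of all TPM in the Cre group and 5.63 ± 0.148% in controls (SD, n = 5 each; exact permutation p = 0.00794, the smallest that 252 labelings allow).

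Among 19 cardiac ion channel genes, 7 fell and 3 rose (8 fell and 3 rose adjusted over the list alone) (camera adjusted p = 6.3e-05; adjusted p = 0.134 with an estimated correlation), and 12 fell and 2 rose under median-of-ratios scaling. The potassium channels Kcnj3 and Kcnd2 fell by 1.82 and 1.27, and the auxiliary subunit Kcne1 rose by 0.72. The intercalated disc list did not pass (camera adjusted p = 0.0612). Of its 16 genes, 5 rose and 5 fell, with Ctnnb1, beta-catenin, up by 0.74 and the desmosomal Dsc2 down by 0.88. Under median-of-ratios scaling 1 of them rose and 9 fell, and the list passed (adjusted p = 0.0356), as it did without Cre 3 or 5 or control 10 or 12 (adjusted p from 0.0333 to 0.0477). It also passed camera with quantile normalization (adjusted p = 0.0352) and at a mean TPM of at least 5 (0.0404). In the fetal and stress-associated cardiomyocyte list, 11 of 16 genes rose and none fell (camera adjusted p = 0.00315; adjusted p = 0.183 with an estimated correlation), 7 under median-of-ratios scaling. The natriuretic peptide gene Nppa was 1483 ± 368 TPM against 234 ± 136 TPM (SD, n = 5 each; log2 difference 2.80, limma adjusted p = 5.34e-05). Ankrd1, a stretch-responsive ankyrin repeat protein, rose by 2.01, skeletal actin Acta1 by 1.61 and filamin C, Flnc, by 0.82. Nppb (448 ± 81.3 against 300 ± 117 TPM, adjusted p = 0.0425) and Myh7 (69.0 ± 19.4 against 44.2 ± 13.4 TPM, adjusted p = 0.0453) passed narrowly in the limma test. Both calls were lost under median-of-ratios scaling, with adjusted p of 0.179 and 0.196. The Nppb call was also lost without Cre 1, 4, 5 or 6 or control 10, 11 or 12, and the Myh7 call without Cre 3, 4 or 6 or control 13 or 16.

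Genes of mitochondrial energy metabolism were lower together, by about as much as the sarcomere genes in the same libraries (medians of the first 3 lists below -0.43, -0.40 and -0.30, sarcomere list -0.43). All 18 genes of the tricarboxylic acid cycle fell (camera adjusted p = 7.67e-15; adjusted p = 0.166 with an estimated correlation), among them Cs by 0.48, Dlst by 0.44 and Sucla2 by 0.63. In fatty acid oxidation 19 of 26 genes fell and none rose (21 fell and 2 rose adjusted over the list alone; camera adjusted p = 3.88e-14, adjusted p = 0.134 with an estimated correlation). Acsl1, which activates long-chain fatty acids, was 138 ± 5.85 TPM against 207 ± 9.17 TPM (SD, n = 5 each; log2 difference -0.58, limma adjusted p = 7.95e-06). Hadha fell by 0.56 and Hadhb by 0.61. Of 46 nuclear-encoded oxidative phosphorylation genes, 33 fell and none rose (38 fell adjusted over the list alone; camera adjusted p = 2.63e-20, adjusted p = 0.245 with an estimated correlation), with Cox6a2 down by 0.73, Uqcrc2 by 0.49 and Uqcrc1 by 0.51. None of the 13 mitochondrially encoded genes passed singly (camera adjusted p = 0.0117; adjusted p = 0.269 with an estimated correlation), and 8 fell under median-of-ratios scaling. The call of that list was lost without the filter on low values (adjusted p = 0.187) and with quantile normalization, where the difference changed sign (adjusted p = 0.618). The most abundant, mt-Atp8, overlaps its neighbour on the mitochondrial genome, which makes its value uncertain. It was 172210 ± 32740 TPM against 183250 ± 8391 TPM (SD, n = 5 each; limma adjusted p = 0.521). The mitochondrially encoded share of TPM was taken over all genes whose symbol starts with mt-, not over this list alone. It was 47.9 ± 4.05% in the Cre group and 50.8 ± 0.887% in controls (SD, n = 5 each; exact permutation p = 0.0714), and 40.9% in the library labelled Cre 4. In the glycolysis list 13 of 20 genes rose and 5 fell, and the set did not pass (camera adjusted p = 0.159), though it did by ranks (adjusted p = 0.0410) and without the filter (adjusted p = 0.00516). The glucose transporter Slc2a1 was 25.1 ± 3.38 TPM against 2.99 ± 0.767 TPM (SD, n = 5 each; log2 difference 2.72, limma adjusted p = 7.31e-08) and Pfkp rose by 1.27. Eno3, Ldhb and the transporter Slc2a4 fell by 1.04, 0.54 and 0.42.

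Genes of the oxidative stress response rose in the Cre group. All 18 targets of NRF2, the transcription factor of antioxidant defence, rose (camera adjusted p = 1.84e-14; adjusted p = 0.134 with an estimated correlation). Txnrd1, thioredoxin reductase, was 137 ± 9.52 TPM against 18.6 ± 1.12 TPM (SD, n = 5 each; log2 difference 2.81, limma adjusted p = 2.59e-10). Gclm, a subunit of the enzyme that starts glutathione synthesis, rose by 2.38, and Hmox1, heme oxygenase, by 2.18. In the p53 target list 15 of 17 genes rose and none fell (camera adjusted p = 2.08e-05; adjusted p = 0.134 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.82, Phlda3 by 1.39 and the apoptosis effector Bax by 1.10. In the integrated stress response list 14 of 21 genes rose and 1 fell (camera adjusted p = 0.0122; adjusted p = 0.314 with an estimated correlation). Besides Gdf15, the serine synthesis enzyme Psat1 rose by 1.04 and Sesn2 by 1.10, while Ddit3 (log2 difference 0.10) and Atf3 (-0.60) did not pass. Sesn2 is also a member of the p53 list, and Gdf15 of the stress-associated list.

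Genes of protein folding and protein breakdown were higher. Of 24 ubiquitin and proteasome genes 21 rose and none fell (camera adjusted p = 3.15e-10; adjusted p = 0.227 with an estimated correlation). The muscle ubiquitin ligase Trim54 was 104 ± 9.10 TPM against 14.9 ± 0.948 TPM (SD, n = 5 each; log2 difference 2.73, limma adjusted p = 5.09e-10), and the proteasome subunits Psmd11 and Psmd1 rose by 1.12 and 0.95. Of 19 heat shock and protein quality control genes 13 rose and none fell (15 rose adjusted over the list alone), including Hspb1 by 0.90, Hsp90aa1 by 0.88 and Hsp90ab1 by 0.63 (camera adjusted p = 0.00523; adjusted p = 0.314 with an estimated correlation). Under median-of-ratios scaling 8 of them rose and 2 fell. In the endoplasmic reticulum unfolded protein response list 11 of 17 genes rose and 1 fell (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.445 with an estimated correlation). Canx rose by 0.54, Pdia4 by 0.57 and Pdia6 by 0.54, and under median-of-ratios scaling 6 of the list rose and 1 fell. That list's call was lost among genes of mean TPM of at least 5 (adjusted p = 0.0651) and with quantile normalization (adjusted p = 0.0506), and that of the integrated stress response among genes of mean TPM of at least 5 (adjusted p = 0.0603).

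The rest of the ESCRT machinery was slightly higher. Of 28 ESCRT genes other than Tsg101, 21 rose and 1, Chmp4c, fell (camera adjusted p = 0.00964; adjusted p = 0.404 with an estimated correlation). Under median-of-ratios scaling 6 rose and 1 fell, where 2445 of all 13049 tested genes rose. The list passed there too at the preset correlation (camera adjusted p = 0.0251). The ESCRT-0 subunit Hgs was 18.7 ± 2.49 TPM against 10.6 ± 1.20 TPM (SD, n = 5 each; log2 difference 0.76, limma adjusted p = 0.000106), and the ESCRT-III subunits Chmp4b and Chmp1b rose by 0.54 and 0.51. Vps28, another ESCRT-I subunit, was 43.8 ± 4.84 TPM against 38.8 ± 1.65 TPM and did not pass. Of 27 endosome trafficking genes 17 rose and 1 fell (camera adjusted p = 0.00934; adjusted p = 0.423 with an estimated correlation), 10 and 3 under median-of-ratios scaling. The retromer subunits Vps26a and Vps29 rose by 0.52 and 0.57, and the sorting nexin Snx2 by 0.60.

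Of 32 lysosomal genes 28 rose and 1, Ctsf, fell (camera adjusted p = 2.52e-08; adjusted p = 0.206 with an estimated correlation). The protease Ctsd was 582 ± 48.0 TPM against 190 ± 7.08 TPM (SD, n = 5 each; log2 difference 1.60, limma adjusted p = 1.52e-08), Cd63, a membrane protein of late endosomes, rose by 1.27 and the glucosidase Gaa by 0.76. Macrophage markers, whose cells are rich in lysosomes, were higher in the same libraries by a mean of 1.30 log2 units. In the autophagy list 14 of 26 genes rose and 1 fell. The receptor Sqstm1 (p62) was 560 ± 38.1 TPM against 94.0 ± 2.76 TPM (SD, n = 5 each; log2 difference 2.56, limma adjusted p = 2.59e-10), Bnip3 rose by 1.60 and Gabarapl1 by 1.04, while Map1lc3a fell by 0.48. As a set it barely passed (camera adjusted p = 0.0434; adjusted p = 0.446 with an estimated correlation). Under median-of-ratios scaling 7 rose and 3 fell and the set did not pass (adjusted p = 0.113), nor did it without Cre 3 or 4 or control 10, 11 or 12 (adjusted p from 0.0509 to 0.0653). Of 23 cholesterol synthesis genes 18 rose, among them Fdps by 1.39 and Cyp51 by 1.33, and none fell (camera adjusted p = 3.35e-05; adjusted p = 0.290 with an estimated correlation).

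Extracellular matrix genes were higher, with 25 of 32 up and 1, Eln, down (camera adjusted p = 1.55e-05; adjusted p = 0.368 with an estimated correlation). With median-of-ratios scaling 19 were up and 2 down. Tenascin C, Tnc, a matrix protein of wounds and developing tissue, was 30.5 ± 6.41 TPM against 4.66 ± 0.698 TPM (SD, n = 5 each; log2 difference 2.46, limma adjusted p = 1.45e-07), Col8a1 rose by 2.15 and Loxl2 by 1.19. Of 46 cytosolic ribosomal protein genes 45 rose (46 adjusted over the list alone; camera adjusted p = 3.04e-11, adjusted p = 0.316 with an estimated correlation), Rpl10a by 0.77, Rpl5 by 0.74 and Rpl4 by 0.64. These genes have many processed pseudogenes, so their values are uncertain. The chemokine genes Ccl2 and Ccl7 rose by 3.06 and 2.64 and Nfkb2 by 0.81, in a list of inflammatory cytokines and NF-kB targets where 10 of 17 rose and 1 fell, in the libraries where macrophage and monocyte markers were also higher. That list missed the threshold (camera adjusted p = 0.0621) and passed under median-of-ratios scaling (adjusted p = 0.0117) and without control 10 or 13 (adjusted p = 0.0146 and 0.0263). It also passed camera without the filter (adjusted p = 0.002), with quantile normalization (0.0140), at a mean TPM of at least 5 (0.0201) and without mitochondrially encoded genes (0.0477).

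The remaining program lists did not pass, though the interferon and immediate early lists did without the filter on low values (adjusted p = 0.0253 and 0.0462). Of 22 interferon-stimulated genes 6 rose (camera adjusted p = 0.407), with Ifi27l2a up by 1.44, Ifit3 by 0.98 and Rsad2 by 0.64. Of 20 immediate early and ERK-responsive genes 8 rose and 3 fell (9 rose adjusted over the list alone; camera adjusted p = 0.407), with Etv4 up by 1.71, Myc by 1.34 and Ier3 by 1.05 and Nr4a1 down by 1.28. Of 30 cell cycle genes 8 rose (6 adjusted over the list alone; camera adjusted p = 0.575), Tyms by 0.59, Mcm6 by 0.45 and Ccnb1 by 0.42, but under median-of-ratios scaling 1 rose and 1 fell. At the deposited scale 4593 of all 13054 tested genes rose and 1296 fell, which also stands beside the counts of the cell type lists below. Rises in the interferon and cell cycle lists were no more frequent than that.

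Markers of other cell types did not move alike. Of 12 macrophage markers 9 rose and none fell (10 rose adjusted over the list alone; camera adjusted p = 2.08e-05, adjusted p = 0.211 with an estimated correlation). The complement gene C1qb was 48.3 ± 8.26 TPM against 12.1 ± 2.07 TPM (SD, n = 5 each; log2 difference 1.90, limma adjusted p = 8.41e-07), Cx3cr1 rose by 1.95 and Mrc1 by 1.56, while Lyve1 (log2 difference 0.10) and Mertk (0.04) did not pass. All 4 tested monocyte markers rose, Ccr2 by 1.63, S100a4 by 1.12 and Plac8 by 0.86, too few for a set test. Of 14 endothelial markers 9 fell and 1 rose (camera adjusted p = 2.08e-05; adjusted p = 0.206 with an estimated correlation), 12 and none under median-of-ratios scaling, with Cdh5 down by 0.48, Robo4 by 0.36 and Tie1 by 0.26. Fibroblast markers went both ways, 5 up and 2 down of 14 (camera adjusted p = 0.798), with Meox1 up by 0.93, Lum by 0.92 and Dcn by 0.69. Of 12 pericyte and smooth muscle markers 4 rose and none fell (camera adjusted p = 0.918), 2 and 2 under median-of-ratios scaling, with smooth muscle actin Acta2 up by 1.05 and Cspg4 by 0.65. The mean of this list was 0.18 and its set statistic pointed down, so its direction is open.

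Of 7 erythroid genes 2 fell (none adjusted over the list alone), the near-identical alpha globins Hba-a2 by 0.48 and Hba-a1 by 0.46 (camera adjusted p = 0.0122; adjusted p = 0.407 with an estimated correlation), and 4 fell under median-of-ratios scaling. The call of that list was lost with quantile normalization (adjusted p = 0.0678). The Hba-a1 call was kept only in the fits without the library labelled Cre 4 or control 12 among those leaving out 1 library, and the Hba-a2 call without the library labelled Cre 4 or control 11 or 12. Of 6 liver genes 4 fell, with Alb at 1.20 to 5.78 TPM in the Cre libraries and 4.47 to 50.1 TPM in controls (camera adjusted p = 0.000696; adjusted p = 0.290 with an estimated correlation). The epicardial and mesothelial list (3 of 5 up and 1 down, camera adjusted p = 0.407) and the atrial cardiomyocyte list (2 of 9 up and 1 down, camera adjusted p = 0.388) did not pass, and the atrial list had a median of -0.03 and a mean of 0.22. The atrial mean beyond that of other genes was 0.052, and 0.774 without control 10, where the list did not pass either (camera adjusted p = 0.253). Lists with fewer than 5 tested genes had no set test. None of 4 neutrophil, 2 T and NK cell, 1 B cell, 2 Schwann cell and 1 lung gene passed, with S100a9, Thy1, Ighm, Cnp and Ager at log2 differences of -0.03, 0.02, 0.35, 0.27 and 0.12. S100a9 was 32.8 TPM in the library labelled Cre 4 and 4.37 to 8.74 TPM in the other Cre libraries. It passed under median-of-ratios scaling without that library (log2 difference -0.63, limma adjusted p = 0.0474). Adjusted over the list alone, Ighm and Cnp passed, but with 1 and 2 tested genes this is no adjustment for Ighm and little for Cnp. Over all genes Ighm passed without Cre 3 (adjusted p = 0.0116) and Cnp without Cre 6 or control 13 (adjusted p = 0.0445 and 0.0256). The adipocyte list had 1 of 3 genes up (Cidea, 0.22) and 1 down (Plin5, -0.54), with 2 up adjusted over the list alone, and the skeletal muscle list 1 of 3 up (Mylpf, 0.69). The Cidea and Mylpf calls were lost under median-of-ratios scaling, with adjusted p of 0.885 and 0.0782. The Cidea call was also lost without Cre 3 or control 10, 12, 13 or 16, and the Mylpf call without Cre 5 or control 12 or 16.

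**Figure D3:**
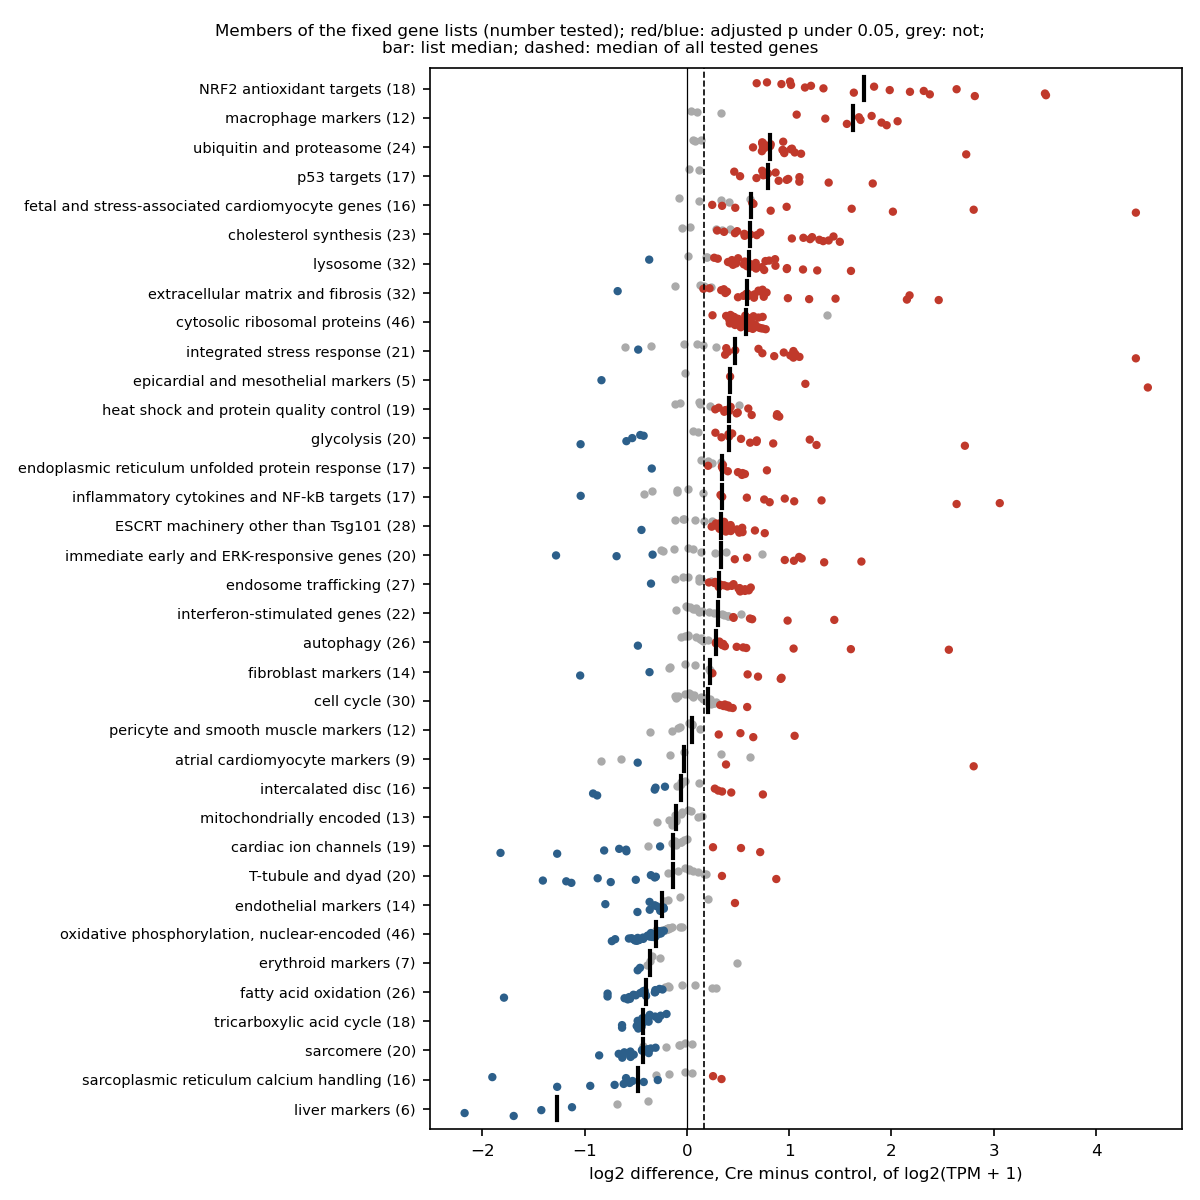
Log2 difference of log2(TPM + 1), Cre minus control, of each tested member of the 36 lists with a set test (1 point per gene), with members past an adjusted p of 0.05 in red (higher) or blue (lower), the list median as a black bar and the median of all tested genes (0.16) as a dashed line. All 18 NRF2 targets lie above 0 and all 18 tricarboxylic acid cycle genes below it, and under median-of-ratios scaling the median of all tested genes moves by -0.18.

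Over the 36 lists tested, 26 passed the camera test with its preset correlation, 15 of them higher and 11 lower, and none passed with an estimated correlation. The self-contained test fry, which asks whether a list's genes move to one side without comparing them with other genes, passed 32. It tests against 0 at the deposited scale, where the median tested gene was 0.16 log2 units higher, so a list at that middle can pass. The fibroblast list did so with a mean of 0.168 (fry adjusted p = 0.00787; camera adjusted p = 0.798). Y-linked genes were expressed in 3 Cre and 2 control libraries, so both groups held male and female hearts, and the 5 sex-linked genes did not pass.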

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

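The tests of the library labelled Cre 4, of the macrophage markers and of mesothelial tissue were chosen after the result was seen, and the test of epithelial tissue before its result was seen, except that the limit set by its low markers was added later. Single libraries were compared with the rest of their group over 296 group values (named genes and library measures). A library stood far from the others of its group in 18 of them, where chance gives about 14.8, and 6 of the 18 are in the library labelled Cre 4.

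In that library Tsg101 was 42.0 TPM (other Cre libraries 26.8 to 31.0), Chmp4b 98.6 TPM (72.8 to 78.7), Ier3 68.2 TPM (48.2 to 50.8), S100a9 32.8 TPM (4.37 to 8.74), Hba-a2 2548 TPM (1343 to 1691) and the mitochondrially encoded share 40.9% (48.8 to 51.4). Elsewhere in the Cre group, Acsl1 in Cre 6 was 128.3 TPM (138.9 to 142.5 in the others), Rpl5 in Cre 6 was 32.5 TPM (35.4 to 36.5), Robo4 in Cre 6 was 10.5 TPM (13.4 to 14.3) and Col8a1 in Cre 1 was 31.98 TPM (16.6 to 20.3). Among controls, control 10 stood apart in Uqcrc2 at 368.5 TPM (391.3 to 399.9), Cs at 362.2 TPM (392.5 to 402.5), Ifit3 at 1.86 TPM (0.427 to 0.759), Dcn at 298.1 TPM (245.6 to 259.8) and Tbx5 at 8.86 TPM (4.77 to 5.80). Control 11 stood apart in Tubb3 at 0.887 TPM (0.316 to 0.429) and Gsta2 at 0.202 TPM (others listed at 0), and control 12 in Loxl2 at 27.2 TPM (30.5 to 31.5).

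The Tsg101 level of the library labelled Cre 4, at 108.5% of the control mean, would follow if a control heart carried the Cre label. Over 557 genes called with at least 1 log2 unit without that library, its median position was 1.036, where 0 is the control mean and 1 the mean of the other Cre libraries, which argues against this. Its low mitochondrial share raises its other TPM values, but after median-of-ratios scaling Tsg101 there was still 36.15 TPM, above the highest other Cre library (28.9 TPM, SD of those libraries 2.09) and below the lowest control (39.6 TPM), so this could account for part of the excess and not for all of it. The other Cre libraries, each placed in the same way, had median positions of 0.865 to 1.064, so the response of that library was not weaker despite its Tsg101 level. Its sarcomere share was 5.00% of TPM, against 3.65 to 4.25% in the other Cre libraries, a value that its low mitochondrial share also raises. Less deletion in that heart, or more Tsg101 from cells that the vector does not reach, stay open as untested, since these values rest on 1 library.

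The mean of the macrophage markers was higher in all 5 Cre libraries than in every control, though 3 of the 12 markers did not pass. A lower cardiomyocyte share would raise the markers of every other cell type alike, but the change of macrophage markers less that of endothelial markers was 1.521 log2 units (exact permutation p = 0.00794, the smallest that 252 labelings allow), which argues against it as the cause. More blood left in the heart would raise the hemoglobin share, but its Cre mean was 0.748 of the control mean. The groups overlapped in this share, at 0.3145 to 0.5968% in the Cre group and 0.4403 to 0.641% in controls (exact permutation p = 0.0635). No rise was seen, which argues only weakly against more blood. More macrophages and more transcript per macrophage cannot be told apart, since marker changes ran from 0.04 to 2.06 log2 units (SD 0.740), which a single macrophage subset could also give. A response of the heart to deletion of Tsg101 or to Cre remains a hypothesis.

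Krt8 and Krt18 are also markers of mesothelium and epithelium, so tissue taken along with the heart could raise them. The median change of 8 mesothelial markers other than keratins was -0.029 log2 units (SD 0.569), under 2.25, which is 0.5 of the Krt8 change, by more than their SD. Had each of them risen 49.5 times, as Krt8 did, it would have been 3.003, so more mesothelial tissue is argued against. Its members differed, since Aldh1a2 rose by 1.16 and Wt1 fell by 0.84. The median of 10 epithelial markers was 0.047 (SD 0.474). Most of them are so low that the same fold would give only 0.822, so this median cannot tell. In TPM the highest of them in the Cre group was Cldn4, far below Krt18 at 188 TPM and Krt8 at 41.5 TPM. The proportions in which such tissue would bring these transcripts were not tested. Epcam was 0.307 TPM in the Cre group against 0.0275 TPM in controls, Cdh1 0.144 against 0.0495 TPM and Cldn4 1.91 against 0.0191 TPM, while Krt19 was 1.221 against 1.228 TPM and Cldn3 0.0333 against 0.120 TPM. Epithelial tissue stays open, as does expression of these keratins within heart cells of the Cre group, which whole-heart RNA does not test.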

How the results depend on the processing

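The alternatives that leave out the library labelled Cre 4 together with a change of scaling, and the one on protein-coding genes only, were chosen after seeing the data. Over the alternatives that refit single genes, the 140 named genes other than Tsg101 kept direction and side of the threshold in 3203 fits, lost the call in 99, gained it in 7 and reversed in 32, and the lists, over all 27 alternatives, in 878, 47, 26 and 16. The count of called genes ran from 4592 (mean TPM of at least 5) to 6198 (first residual component as covariate). No paired analysis was possible because the groups share no replicate numbers. The fits listed in advance for raw counts were not run, since the values are TPM. Depth is unknown, so its limit on low genes was not measured. The cause was not tested for any of the changes below unless stated.

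The higher and lower calls were 2445 and 2572 under median-of-ratios scaling, 2553 and 2504 under quantile normalization, and 2456 and 2429 under median-of-ratios scaling without the library labelled Cre 4. These scalings recentre the libraries by construction. Rescaling without mitochondrially encoded genes gave 3803 and 1685 (69.3% higher), and protein-coding genes only 3604 and 1653 (68.6% higher). Genes past 1 log2 unit numbered 219 with a pseudocount of 5 TPM, which shrinks low genes by construction, and 369 at a mean TPM of at least 5, where fewer genes (8525) are tested. With an estimated correlation 0 lists passed camera, where 26 passed with the preset one, 26 by ranks and 32 by fry. Tsg101 missed the threshold without the filter (log2 difference -0.326, adjusted p = 0.0668, with 29107 genes tested), and its adjusted p ran from 2.8e-05 to 0.0698 over all alternatives. Leaving out each library in turn gave -0.436 to -0.279 for Tsg101, 5316 to 5683 called genes and 25 to 27 lists.

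Genes that reversed had not passed, except Cidea. Under median-of-ratios scaling Cav3 was -0.152, Cacna1c -0.186 and Thy1 -0.177, under quantile normalization -0.175, -0.179 and -0.167, without mitochondrially encoded genes -0.021, -0.058 and -0.054, and with protein-coding genes only -0.036, -0.073 and -0.069. Cav3 was -0.0099 with array weights. With the library labelled Cre 4 left out too, median-of-ratios scaling gave Cav3 -0.216 (adjusted p = 0.0324), Cacna1c -0.120, Thy1 -0.111, Cidea -0.0092, Ager -0.045 and the cell cycle list -0.0012, and rescaling without mitochondrially encoded genes gave Cav3 -0.070. S100a9 was 0.031 with a pseudocount of 5 TPM. With 1 library left out, Cav3 ran from -0.039 to 0.115, Cacna1c from -0.022 to 0.068, Thy1 from -0.033 to 0.058, mt-Atp8 from -0.176 to 0.019 and S100a9 from -0.474 to 0.190.

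In some lists the direction of the set statistic reversed. The values given are mean log2 differences beyond that of other genes, which can differ from it in sign and in the main fit were 0.0088, 0.052, 0.878, 0.184 and -0.234 in the order below. These lists were pericyte and smooth muscle (0.090 without the filter, 0.034 without mitochondrially encoded genes and the library labelled Cre 4, -0.058 to 0.052 with 1 library left out), atrial (0.629 at a mean TPM of at least 5, -0.096 to 0.774 with 1 library left out), epicardial and mesothelial (0.398 without the filter), immediate early (0.032 at a mean TPM of at least 5) and mitochondrially encoded (0.036 under quantile normalization). By fry, whose value is the mean log2 difference itself, pericyte and smooth muscle were 0.176 and atrial 0.219.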

Other observations

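The gene groups in the next 2 paragraphs were chosen after the data were seen, some around genes already among the largest increases, so they are given as counts without a set test. All 3 metallothioneins rose, Mt1 from 110.5 ± 7.46 to 348.1 ± 58.4 TPM (SD, n = 5 each) and Mt3 by 2.54 log2 units. Of 19 glutathione S-transferases 11 rose and 2 fell, with Mgst1 up by 2.96, and under median-of-ratios scaling 11 rose and 4 fell. In the pentose phosphate pathway, which makes NADPH, 5 of 8 genes rose and none fell, with Pgd at 116 ± 11.7 TPM against 22.1 ± 1.15 TPM (SD, n = 5 each). Of 12 alpha and beta tubulins 9 rose and 2 fell, with Tuba1c up by 1.34, while the muscle form Tuba8 fell by 1.21. Of 18 cytosolic aminoacyl-tRNA synthetases 17 rose, with Nars up by 0.78, and 12 rose under median-of-ratios scaling. Several of these genes have close paralogs, so the values of single members are uncertain.

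In 3 groups of cardiac identity and signalling more genes fell than rose. Of 14 cardiac transcription factors 7 fell and 1, Gata4, rose, with Hopx at 117 ± 21.4 TPM against 281 ± 24.2 TPM (SD, n = 5 each). Under median-of-ratios scaling 12 fell and none rose. Of 18 nuclear receptors 9 fell and 5 rose, and 11 fell and none rose under median-of-ratios scaling, with the mineralocorticoid receptor Nr3c2 down by 1.05. Of 11 G protein-coupled receptors 4 fell and 3 rose, and 7 fell and 2 rose under median-of-ratios scaling, with the muscarinic receptor Chrm2 down by 1.41, the adrenergic receptor Adra1b by 1.25 and the angiotensin receptor Agtr1a by 1.20. Of 17 genes of branched-chain amino acid breakdown 7 fell and none rose, and 15 fell under median-of-ratios scaling. Of 3 creatine kinases the muscle form Ckm fell by 0.93 and the mitochondrial form Ckmt2 by 0.60, while the brain form Ckb rose by 0.36, a rise that was lost under median-of-ratios scaling.

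The 10 libraries can be split into 5 and 5 in 126 ways, and 100 of these were fitted, the real one included. Only the real split, 1 of the 100, reached its 5889 calls. The highest other split gave 1 call and their median was 0. Each other split mixes the groups, so the group difference widens its spread and lowers its calls. The low counts therefore do not measure how many calls chance would give. The split of the libraries by expression of Y-linked genes, fitted apart from these, gave 5 calls. Since that split was made from Y-linked genes, calls of such genes follow from its making. The 5 values of one group lay wholly above or below those of the other in 33.1% of tested genes, where chance gives 0.794% for a single gene. The Cre group was above in 3464 of them and below in 852. This split is at the deposited scale, where the median tested gene was 0.16 log2 units higher in the Cre group.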
